A study of Caenorhabditis elegans with 18 samples.

How the data were processed

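LEM-2 chromatin immunoprecipitation followed by sequencing (ChIP-seq) was compared with input chromatin in early Caenorhabditis elegans embryos of 3 strains, the wild type N2 and the mutants met-2(n4256) and set-25(n5021), at 20 degrees. Per the labels, each strain had 3 IP and 3 input libraries from independent biological replicates, which makes 18 libraries in 6 groups. Per the series' design text, the libraries were made without size selection and sequenced in pairs.

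The deposited table holds a value on the log2 scale for each of 200538 windows of 500 bp over the 6 nuclear chromosomes, with 1 column per library and no mitochondrial windows. The values themselves show how they were made. Each is log2 of the scaled reads of a window plus 2, the lowest value is 1 in every column, and every library was scaled to 35.17 M reads. Because each column has a single step, whole reads could be recovered for 100.0% of the values of every library, within 0.01 of a whole number. All 18 recovered totals were even, as they are when both ends of each pair are counted. The aligner, the counting tool, the treatment of duplicate reads and any filter are not given in the sources used here. Scaling every library to the same total makes all values relative: a change over much of the genome is balanced by an opposite one elsewhere. Reads that map to repeats may have been kept or dropped before the table was made.

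The submitters' processing notes name the build ce10, but the windows of the table end at other chromosome lengths than that build has. Coordinates are therefore given as in the deposited table. The gene table at hand belongs to another build, so no bin was assigned to a gene and no test of genes or gene lists was made.

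Columns name the strain, the kind of library and a letter from a to c, and not the replicate number of the labels. Each column was therefore used as a replicate of its group with no number. LEM-2 enrichment of an IP library was its log2 value minus the mean of the 3 inputs of its strain, whereas the choice made before the data were examined was the input of the same number. Window values were averaged over 10029 bins of 10 kb. A minimum of 10 mean input reads removed 0 of these bins and 36 of the 500-bp windows. Replicates were compared in pairs: in 18 pairs within groups, the chi-square of reads per bin was between 6.71 and 86.5, so no pair agreed within sampling noise.

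Each chromosome was divided by its length in the table into left, middle and right parts of equal size. The arm contrast was the mean enrichment of the outer parts of the autosomes minus that of their middle parts. The X left contrast was the mean of the left part of X minus that of the rest of X. Both were compared between strains by exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries, with Benjamini-Hochberg adjustment over 6 comparisons. The 3 values of a strain share 1 input mean, so they are not fully independent and their SD leaves out the spread of the inputs. This holds wherever the enrichments of single libraries are compared. Bins were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, 1 coefficient for each of the 6 groups, all 18 libraries, 12 residual degrees of freedom). The contrast was the difference in IP minus input between 2 strains, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test had been set for log2 values before the data were examined. The 18 chromosome parts were tested with limma's fry, a self-contained test of whether the bins of a part move one way on balance, and with camera with an estimated correlation, which compares a part with the other bins. Bins were also divided into 5 classes of equal size by their mean enrichment over all 9 IP libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

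The comparisons, tests, chromosome parts and classes were also chosen before the data were examined, as was the rule for named bins: for each comparison, the 5 largest rises and 5 largest falls among bins past an adjusted p of 0.05 whose 3 values in one strain all lay beyond all 3 of the other, at most 1 per 100 kb. To check the strain labels, windows were sought that held at most 5% of the library's median window in some inputs and at least 50% in all others, levels chosen after the data were seen.

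The test of bins was tested on simulated data for met-2 against N2, with the 10029 bins and the spread of the real libraries. Simulated bins were independent of each other. Of 50 bins changed by 0.25 on the log2 scale, 2% were recovered, against 46% at 0.5, 90% at 1 and 100% at 2, and 5.56% of the calls were false. A simulated comparison without change gave 0 calls. Only 50 bins were changed at each size, against 6816 bins that passed in the real comparison of met-2 with N2. The adjusted threshold is stricter when few bins change, so these rates do not describe recovery in the real comparison.

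Depth after recovery ran from 8.73 to 41.92 M reads per IP library with a median of 29.07 M, and from 32.32 to 64.45 M per input with a median of 45.37 M. The median 10-kb bin held 799 reads in the shallowest library and 6118 in the deepest. Alternatives tried were median centring, windows of 500 bp and bins of 50 kb, IP libraries alone, blocks by column letter, each replicate left out, other pseudocounts on recovered reads, outer parts of 25% each, medians over bins, and a minimum change of 0.5. Chosen after the data were seen were limma voom on recovered reads, a pseudocount of 1 CPM, fits without the libraries whose coverage did not match the rest of their strain, and median centring and left-out replicates for the chromosome parts and classes.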

Results

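LEM-2 is a protein of the inner nuclear membrane, and its ChIP-seq signal shows which parts of the genome lie at the nuclear periphery. The series title names a cofactor of MET-2, H3K9me2 and anchoring at the periphery. MET-2 and SET-25 are the histone methyltransferases that make these marks in embryos: MET-2, the homologue of SETDB1, makes mono- and dimethylation of H3K9, and SET-25 trimethylation. The comparison asks how LEM-2 contact is distributed when either enzyme is missing. The data were 18 libraries from early embryos, 3 LEM-2 IP and 3 input libraries for each of N2, met-2 and set-25. They are named here by strain and by the letter of their column. The shallowest library was met-2 IP b with 8.73 M reads, and the deepest was set-25 input a with 64.45 M.

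The strain labels were checked first, through windows that some libraries lack altogether. The labels place both mutant alleles on chromosome III, and 2 intervals there were missing in mutants. Chromosome III from 13287501 to 13289000 was missing in all 6 libraries labelled set-25, at 0 to 0.58% of the library's median window, and present in the 12 others at 70.75% or more. Chromosome III from 8376501 to 8377500 was missing in all 6 met-2 libraries. It was also missing in the 4 libraries of columns b and c labelled set-25, IP and input alike. These 10 libraries held 0 to 5 reads there, while set-25 input a held 684 reads and N2 inputs a, b and c held 435, 358 and 425. The libraries labelled set-25 were therefore not alike: column a carried the interval that met-2 lacks, and columns b and c did not. They are called the libraries labelled set-25 below, with the value of each column where it matters. The N2 libraries were not alike either. On chromosome V from 1646001 to 1647500, N2 column a held 4 IP reads and 0 input reads, while N2 inputs b and c held 471 and 541. Columns b and c labelled set-25 also lacked this interval.

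**Figure D1:**
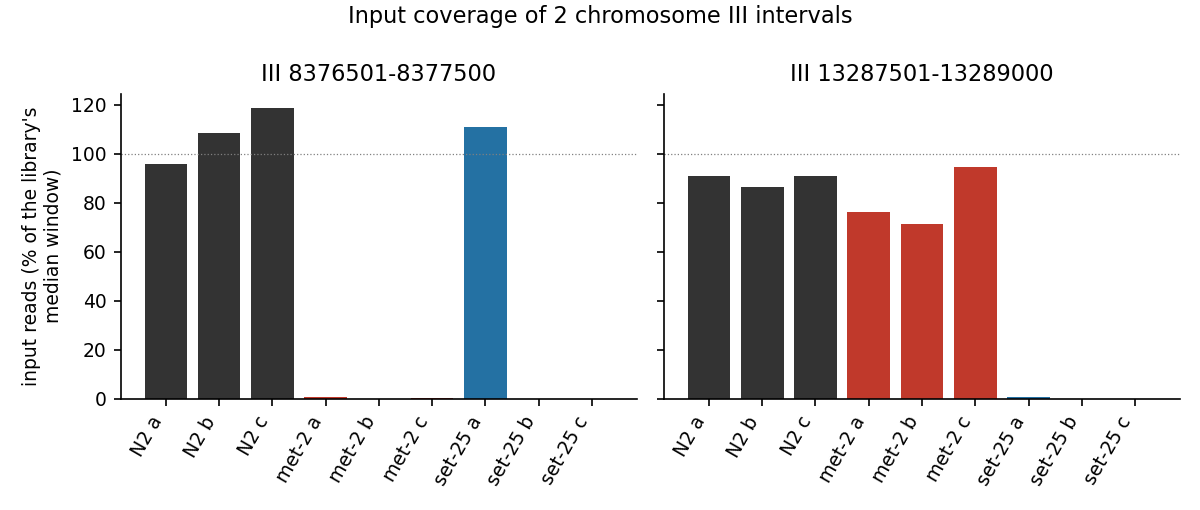
Input reads in 2 intervals of chromosome III, in percent of the library's median window, for the 9 input libraries (bars, 1 per library; black N2, red met-2, blue labelled set-25; the dotted line is 100%). Inputs b and c labelled set-25 held no reads in either interval, while input a held 684 reads in the left one.

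In N2 embryos, LEM-2 was on average enriched on the outer parts of the autosomes other than the right part of II, and depleted over their middle parts. The right part of II was at -0.04 ± 0.02 (SD, n = 3). The arm contrast was 0.95 ± 0.21 on the log2 scale (SD, n = 3), a ratio of 1.93, with 1.20, 0.83 and 0.83 in columns a, b and c. The middle parts of chromosomes I, II and III were lowest, at -0.93 ± 0.22, -0.87 ± 0.21 and -0.98 ± 0.23, and those of IV and V lay at -0.62 ± 0.11 and -0.64 ± 0.12 (SD, n = 3). The right part of V, the left part of III and the right part of IV were highest, at 0.28 ± 0.06, 0.28 ± 0.04 and 0.27 ± 0.06. On X the means of the left, middle and right parts were -0.31 ± 0.05, -0.62 ± 0.11 and -0.36 ± 0.07, and the left contrast was 0.19 ± 0.04 (SD, n = 3).

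By limma with a Benjamini-Hochberg adjusted p under 0.05, IP differed from input in 8606 of 10029 bins in N2, with 3243 bins enriched and 5363 depleted. Among the 2754 bins of the autosomal middle parts, 2477 were depleted and 60 enriched, while among the 5503 bins of the outer parts, 2979 were enriched and 1603 depleted. On X, 1283 of 1772 bins were depleted and 204 enriched. On median-centred values, where centring brings the median change to 0.03, the genome-wide split was 4334 enriched and 4139 depleted. The balance of enriched and depleted bins over the genome thus depends on the scaling. Fry called 17 of the 18 parts in N2, all but the right part of II, and camera with an estimated correlation called 0 of 18 (adjusted p = 0.11 to 0.48, 2 at an unadjusted p under 0.05).

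**Figure D2:**
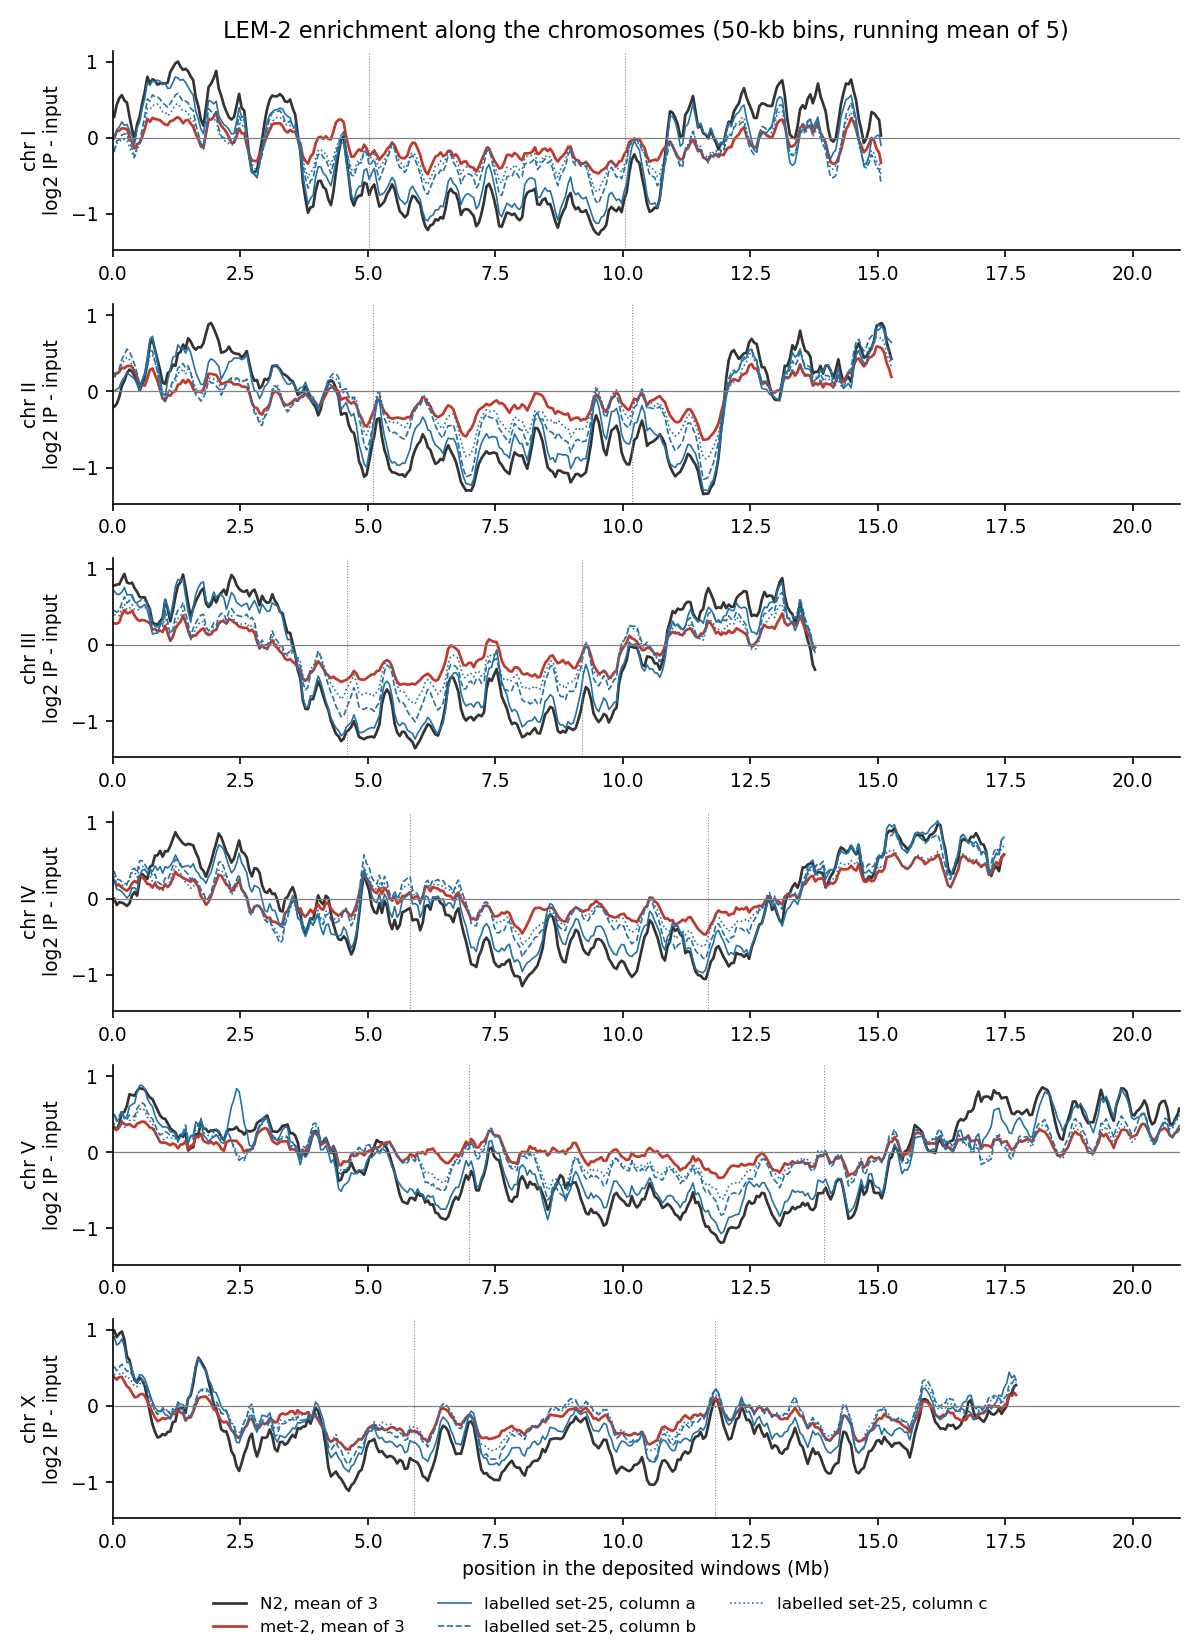
LEM-2 enrichment (log2 IP minus input, vertical axis) in 50-kb bins along the 6 chromosomes (position in Mb), smoothed by a running mean of 5 bins. Lines are means of 3 libraries for N2 (black) and met-2 (red) and single libraries labelled set-25 (blue, columns a, b and c), and dotted lines separate the left, middle and right parts. The deep middle valleys of N2, at -0.98 in the middle part of III, were shallower in met-2, at -0.30.

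In met-2 embryos the difference between arms and centres was much weaker. The arm contrast fell to 0.26 ± 0.07 (SD, n = 3), with 0.17, 0.29 and 0.31 in columns a, b and c. This was 27.03% of the N2 value. It was 31.5% of the N2 value of 0.82 without N2 column a, which lacked the chromosome V interval. The difference from N2 was -0.69, and -0.56 without N2 column a. All 3 met-2 libraries lay below all 3 N2 libraries. Since the libraries of a strain share 1 input mean, a difference between inputs would move all 3 values of a strain at once. The middle parts of I, II, III, IV and V rose by 0.67, 0.63, 0.68, 0.46 and 0.58 on the log2 scale, so that the middle part of V reached -0.07 ± 0.04 (SD, n = 3). Several outer parts fell, most of all the right part of I, by 0.24 from 0.16 ± 0.06 to -0.07 ± 0.05, and the left part of III, by 0.23 from 0.28 ± 0.04 to 0.05 ± 0.02 (SD, n = 3).

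Of the outer parts of the autosomes, 3 did not pass the test, and whether parts differed in their change was not tested. The right part of IV was at 0.27 ± 0.06 in N2 and 0.23 ± 0.05 in met-2 (SD, n = 3), with an adjusted p of 0.66 in fry. The right part of II had an adjusted p of 0.46 and the left part of V 0.50. On median-centred values all 3 passed as lower in met-2, at -0.25, -0.13 and -0.17 (fry, adjusted p = 0.0046, 0.0065 and 0.0017), while camera with an estimated correlation called 0 of 18 parts on total scaling (adjusted p = 0.074 to 0.88, 6 at an unadjusted p under 0.05). On X, the left contrast was 0.02 ± 0.01 in met-2, against 0.19 ± 0.04 in N2 (SD, n = 3), again with no overlap between the strains. On total scaling the left, middle and right parts of X changed by 0.13, 0.38 and 0.21, so the left part rose less than the rest. On median-centred values they changed by -0.07, 0.17 and 0.0067. The size of the X left contrast depended on the measure. With outer parts of 25% it was 0.11 in met-2 and 0.37 in N2, and with medians over bins -0.0035 and 0.10, with no overlap in either. For both contrasts the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give, and 0.12 after adjustment over 6 comparisons. Within column letters, the arm contrast of met-2 differed from that of N2 by -1.02, -0.55 and -0.52, which had to lie below 0 with no overlap between the strains.

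By limma, 6816 of 10029 bins differed between met-2 and N2, of which 4577 were higher and 2239 lower in met-2. In the autosomal middle parts 2490 of 2754 bins were higher and 6 lower. In the outer parts 1158 of 5503 were higher and 2118 lower. The bin with the largest rise spanned 12230001 to 12240000 on V, in the middle part, and went from -1.32 ± 0.22 in N2 to -0.16 ± 0.07 in met-2 (SD, n = 3; change 1.16, SE 0.15, adjusted p = 0.000128). Others lay on III at 5990001 to 6000000 and 8820001 to 8830000, with rises of 1.13 and 1.12, on II at 7060001 to 7070000, with 1.11, and on I at 4270001 to 4280000, with 1.10. The largest fall was on III at 2920001 to 2930000, from 0.60 ± 0.16 to -0.37 ± 0.27 (SD, n = 3; change -0.97, SE 0.27, adjusted p = 0.00453). Bins on the right part of I at 10960001 to 10970000 and 14980001 to 14990000 fell by 0.97 and 0.96. Near the left end of X, the bin from 130001 to 140000 fell by 0.93, from 1.27 ± 0.12 to 0.34 ± 0.03 (SD, n = 3), and on V the bin from 17100001 to 17110000 fell by 0.93.

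The median bin was 0.20 higher in met-2 than in N2. The cause of this shift was not tested, and which bins are unchanged is not known, since all values are relative to the library's total. Relative to the median bin, on median-centred values, the split was 2984 bins higher and 3434 lower. The middle parts of I to V were then higher by 0.46, 0.42, 0.47, 0.25 and 0.37, and the right part of I was lower by -0.44. The left part of X, higher by 0.13 on total scaling, was at -0.07 on median-centred values and no longer passed (fry, adjusted p = 0.14). Nor did the right part of X, which went from 0.21 to 0.0067 (adjusted p = 0.97). The values of the right part of II and the left part of V also changed sign, from 0.08 to -0.13 and from 0.04 to -0.17. On total scaling fry called 15 of 18 parts, 8 higher and 7 lower, and on median-centred values 16, with 6 higher and 10 lower. Camera with an estimated correlation called 0 of 18 (adjusted p = 0.074 to 0.88, 6 at an unadjusted p under 0.05).

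**Figure D3:**
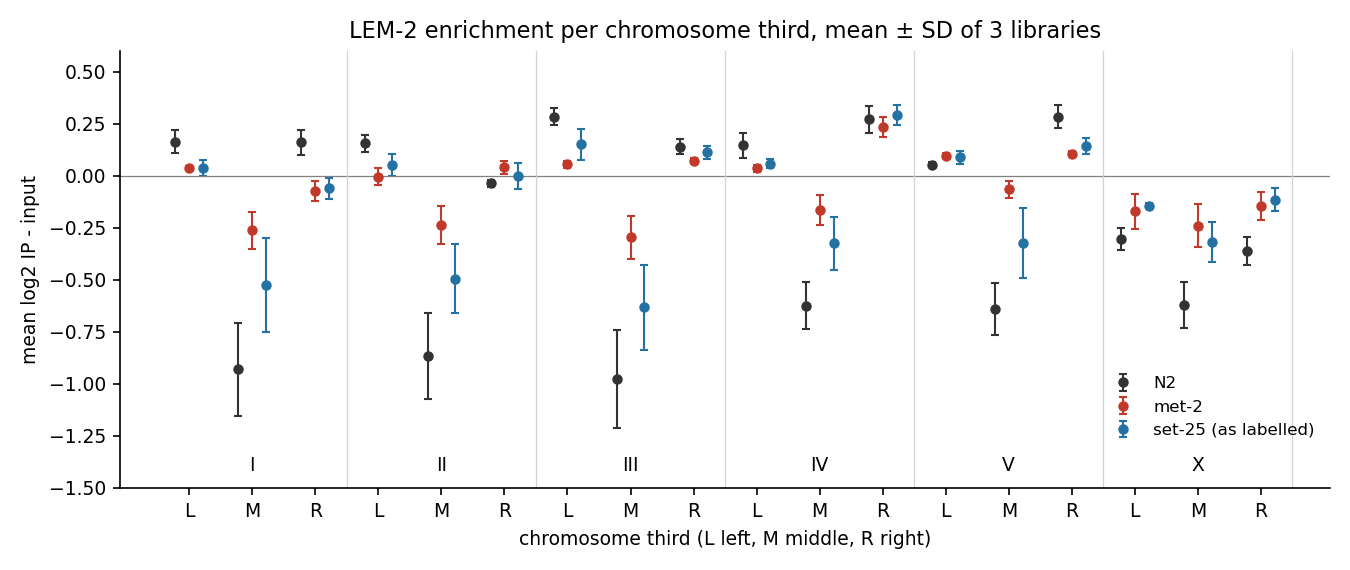
Mean LEM-2 enrichment (log2 IP minus input, vertical axis) of the left, middle and right part of each chromosome (horizontal axis) for N2 (black), met-2 (red) and libraries labelled set-25 (blue). Points are means and bars SD over 3 libraries. The middle part of III was at -0.98 in N2, -0.63 in libraries labelled set-25 and -0.30 in met-2. Columns a, b and c labelled set-25 were at -0.85, -0.60 and -0.45 there, and column a lay within the N2 range.

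In the arm contrast, the libraries labelled set-25 lay between N2 and met-2. Their arm contrast was 0.53 ± 0.19 (SD, n = 3), 56.2% of the N2 value and -0.42 from it. Column a, which carries the interval that met-2 lacks, was at 0.74, and columns b and c, which lack it, were at 0.49 and 0.37. The lowest N2 library was at 0.83. The middle parts of I, II and III lay at -0.53 ± 0.22, -0.50 ± 0.17 and -0.63 ± 0.20, with a change from N2 of 0.41, 0.37 and 0.34. On median-centred values these changes were 0.25, 0.22 and 0.19, and did not pass (fry, adjusted p = 0.069, 0.053 and 0.15). Without N2 column a and columns b and c labelled set-25, the changes of I and III turned direction, to -0.0093 and -0.014. In the middle part of III column a, at -0.85, lay within the N2 range of -1.25 to -0.83, so the groups overlapped there. The right part of I was lower by -0.22 and the right part of V by -0.14. These changes were -0.38 and -0.30 on median-centred values, -0.14 and -0.09 with column a alone, and -0.10 and -0.05 without N2 column a as well. The right part of IV was at 0.29 ± 0.05, against 0.27 ± 0.06 in N2 (SD, n = 3). The X left contrast was 0.16, 0.03 and 0.03 in columns a, b and c, against 0.16 to 0.23 in N2, whose lowest library lay just above column a. On total scaling the mean left, middle and right parts of X were higher than in N2 by 0.16, 0.30 and 0.25, the left part by the least. For both contrasts the exact two-sided permutation p was 0.1, the smallest possible, and 0.12 after adjustment. The X left contrasts overlapped without N2 column a (exact permutation p = 0.3), without column c labelled set-25 (p = 0.2), with outer parts of 25% (p = 0.2) and with medians over bins (p = 0.2). Within column letters, the arm contrast of libraries labelled set-25 differed from that of N2 by -0.45, -0.34 and -0.46. With no overlap between the groups these differences had to lie below 0.

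By limma, 3047 bins differed between the libraries labelled set-25 and N2, 1988 higher and 1059 lower. Bins in the autosomal middle parts were higher in 1053 of 2754 and lower in 6, and in the outer parts higher in 418 of 5503 and lower in 1031. Without columns b and c this strain had 1 library and no spread of its own. In that fit 0 bins passed in limma, with 681 at an unadjusted p under 0.05, and the arm contrast differed from N2 by -0.175. Without N2 column a as well, it differed by -0.041. The median bin was 0.18 higher than in N2, and 0.06 higher with column a alone. On median-centred values 1951 bins passed, 303 higher and 1648 lower.

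The largest falls among bins lay on the arms. On V at 17150001 to 17160000, enrichment was 0.60 ± 0.08 in N2 and -0.46 ± 0.27 in libraries labelled set-25 (SD, n = 3; change -1.06, SE 0.13, adjusted p = 0.000179). On I at 2040001 to 2050000 it was 0.70 ± 0.09 and -0.30 ± 0.11 (SD, n = 3; change -1.0, SE 0.10, adjusted p = 8.81e-05). Further falls of -0.94, -0.94 and -0.92 were on II at 2020001 to 2030000 and 1920001 to 1930000 and on V at 17510001 to 17520000. The largest rises, between 0.65 and 0.68, were on I at 7940001 to 7950000 and 5710001 to 5720000, on II at 5860001 to 5870000 and 7440001 to 7450000, and on III at 9190001 to 9200000. With column a alone the 5 falls were between -0.59 and -0.89 and the 5 rises between 0.30 and 0.49, and 0 of the 10 passed in limma with that 1 library. Of the 10 bins 6 passed without N2 column a, without column b or without column c labelled set-25.

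Fry called 14 of 18 parts for libraries labelled set-25 against N2, 8 higher and 6 lower, and camera with an estimated correlation only the right parts of I and V (adjusted p = 0.037 for both, up to 0.55 for the others). On median-centred values fry called 13 parts, 4 higher and 9 lower, and the values of the right parts of II and IV and the left part of V changed sign, from 0.03, 0.02 and 0.04 to -0.12, -0.13 and -0.12. The left part of X went from 0.16 to 0.0066 and no longer passed (adjusted p = 0.48). With column a alone, 1 library, fry called 0 parts (1 at an unadjusted p under 0.05), and the middle parts of I, II and III differed from N2 by 0.13, 0.18 and 0.12. Fry called 3 parts without N2 column a, without column b or without column c labelled set-25. The count of bins also moved with single libraries. It was 192 without column b labelled set-25 (22 higher, 170 lower), 228 without column c (28 higher, 200 lower), 268 without N2 column a (47 higher, 221 lower), 1540 without met-2 column b, which enters the shared spread, 2000 without N2 column b and 5592 without column a labelled set-25.

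**Figure D4:**
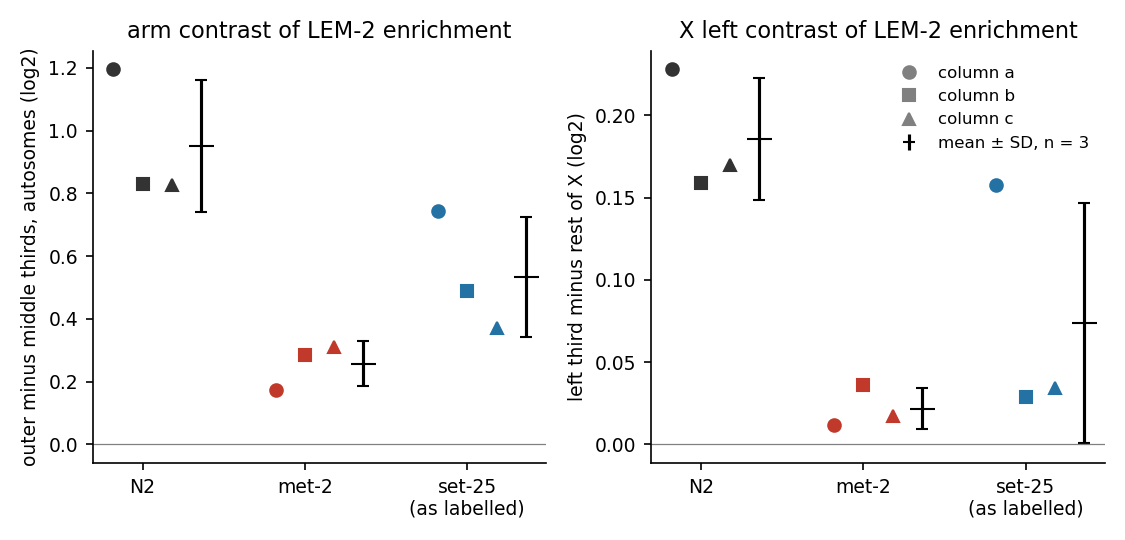
Arm contrast (left panel) and X left contrast (right panel) of LEM-2 enrichment on the log2 scale for each IP library (symbols by column letter) with the mean and SD of 3 libraries, for N2, met-2 and libraries labelled set-25. In the arm contrast the 3 met-2 libraries, at 0.17 to 0.31, lay below all others, and column a labelled set-25 was at 0.74.

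In the arm contrast, met-2 was lower than the libraries labelled set-25 by -0.28, with no overlap. The exact two-sided permutation p was 0.1, and 0.12 after adjustment. Columns b and c labelled set-25 lack the interval that met-2 lacks, so the tests of this pair mix unlike libraries. Without column a labelled set-25 the difference was -0.16, and with that column alone -0.52. Within letters a, b and c the difference was -0.57, -0.20 and -0.06, and had to lie below 0 because the groups did not overlap. The X left contrasts overlapped (exact permutation p = 0.3). By limma, 42 bins differed, 39 higher and 3 lower in met-2, and 28 of the 39 lay in autosomal middle parts. The largest was on V at 8560001 to 8570000, at 0.15 ± 0.06 in met-2 and -0.70 ± 0.27 in libraries labelled set-25 (SD, n = 3; change 0.85, SE 0.13, adjusted p = 0.00706). Other rises were on V at 8840001 to 8850000, with 0.82, on II at 7030001 to 7040000, with 0.79, on III at 8850001 to 8860000, with 0.78, and on I at 4370001 to 4380000, with 0.74. Lower bins were on I at 1280001 to 1290000, with -0.56, and on II at 15170001 to 15180000, with -0.53.

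No part passed for this pair in fry (0 of 18, lowest adjusted p = 0.27, 3 at an unadjusted p under 0.05) or in camera with an estimated correlation (0 of 18, lowest adjusted p = 0.51, 1 unadjusted). With column a as the 1 library labelled set-25 the count was 1443 bins, which cannot separate that library from its strain. It was 0 without met-2 column a or without column b labelled set-25, 2 without met-2 column b, 22 without column a labelled set-25, 162 without met-2 column c and 223 without column c labelled set-25. Through the shared spread it was 367, 17 and 24 without N2 columns a, b and c. In limma the counts at an unadjusted p under 0.05 were 1077 and 1647 where 0 passed. Of the 7 named bins 0 passed without met-2 column a, met-2 column b or column b labelled set-25, and 1 without column a labelled set-25. By voom on recovered reads 1103 bins differed.

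Bins were also compared by class of mean LEM-2 enrichment over all 9 IP libraries. These classes hold the compared libraries, and N2, with an SD over bins of 0.65 to 0.86 against 0.22 to 0.43 in met-2, weighs most in them, so a flatter profile in met-2 gives a gradient over classes by construction. In the class of lowest enrichment, 2006 bins, N2 was at -1.14 ± 0.22 and met-2 at -0.45 ± 0.18 (SD, n = 3), a change of 0.68. In the next classes the change was 0.45, 0.19 and -0.14. In the class of highest enrichment, where 94.72% of bins lay on autosomal outer parts, N2 was at 0.81 ± 0.12 and met-2 at 0.39 ± 0.10 (SD, n = 3), a change of -0.42. For the libraries labelled set-25 the changes from N2 ran from 0.35 in the lowest class to -0.22 in the highest. On median-centred values the changes in the lowest and highest class were 0.48 and -0.63 in met-2, and 0.20 and -0.37 in libraries labelled set-25.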

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

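All tests in this part were chosen after the result was seen. In the windows of chromosome III from 8376501 to 8377500, 10 libraries had no more than 5 reads, 6 labelled met-2 and 4 labelled set-25 (columns b and c). A swap of labels with met-2 would leave reads in the windows that column a labelled set-25 lacks, and the 4 libraries of columns b and c held at most 0.0% of the median window there. A mixture of met-2 and set-25 chromatin would make the levels of the 2 intervals sum to near the median window, and the highest sum was 0.43%. The 4 libraries held 0 to 1 reads in the interval from 8376501 and 0 in that from 13287501. That 4 of the 4 libraries lacked both intervals is thus what was observed, and columns b and c cannot be taken as chromatin that lacks only the set-25 interval. The labels give no strain that lacks both. How these libraries came to lack both intervals was not tested.

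A segment of chromosome V from 2350001 to 2560000 had unequal input coverage among libraries of the same strain. Relative to the library's median bin it was 0.414 in N2 input a, 0.747 in set-25 input b and 0.8 in set-25 input c, and 1.492 to 1.848 in the other 6 inputs. Flanks of 250 kb lay at 0.867 to 0.954 in the 9 inputs. These 21 bins are part of the comparisons, and their enrichment is set partly by this coverage, because inputs were averaged per strain. On chromosome V from 1646001 to 1647500, 6 libraries had at most 4 reads: IP and input of N2 column a and of columns b and c labelled set-25. The other 12 libraries held 155 to 862 reads there.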

How the results depend on the processing

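Settings without N2 column a or columns b and c labelled set-25, voom, a pseudocount of 1 CPM, and median centring or left-out replicates for chromosome parts and level classes were chosen after the data were seen. The arm contrast of set-25 minus N2 shrank to -0.175 without columns b and c labelled set-25 and to -0.041 without N2 column a as well. With each replicate left out the arm contrasts ran from -0.77 to -0.56, from -0.54 to -0.28 and from -0.38 to -0.16 for met-2 minus N2, set-25 minus N2 and met-2 minus set-25. Without N2 column a and columns b and c labelled set-25, the X left contrast of set-25 minus N2 reversed to 0.017. For met-2 against N2, 31414 of 200502 windows of 500 bp passed, 1539 of 2008 bins of 50 kb and 3967 bins at a change of at least 0.5. Camera with an estimated correlation called 0 parts (6 unadjusted). For libraries labelled set-25 against N2 the counts were 1951 with median centring, 3 windows of 500 bp (31125 at an unadjusted p under 0.05), 1094 bins of 50 kb, 669 at a change of at least 0.5, 0 without columns b and c, and 0 also without N2 column a (681 and 636 unadjusted). Parts called by fry were 0 and 0 without these libraries (1 and 1 unadjusted), and 2 by camera. For met-2 against set-25 they were 0 windows of 500 bp (17213 unadjusted), 84 with IP alone, 1103 by voom, and 1443 and 3481 without columns b and c and also without N2 column a, where 2 and 8 parts passed. Fits without columns b and c hold 1 library labelled set-25.

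With each replicate of a pair's own strains left out, bins ran from 5331 to 6713, from 192 to 5592 and from 0 to 223 for the 3 pairs, and parts from 12 to 15, from 3 to 15, and 0. With a replicate of the remaining strain left out, bins ran from 6563 to 7045, from 1540 to 3018 and from 17 to 367. On median-centred values the left part of X in met-2 was reversed to -0.074 and the highest class of met-2 moved to -0.63. Without N2 column a and columns b and c, the middle parts of I and III and the left part of II reversed for set-25, to -0.0093, -0.014 and 0.028. The cause was not tested.

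Same-letter libraries deviated together in part. The correlation of deviations was over 0.1 in 5 of 9 pairs of IP and input (-0.48 to 0.31), 3 of 9 pairs of IP from different strains (-0.54 to 0.65) and 7 of 9 pairs of inputs from different strains (-0.36 to 0.83). It was not over 0.1 in every pair, so letters were not taken to pair libraries. It differed by strain: IP and input were at 0.284, 0.242 and 0.309 in N2, -0.186, -0.345 and -0.481 in met-2, and 0.01, 0.139 and 0.164 in set-25. The 3 pairs of IP over 0.1 were those of set-25 with N2. Of the 9 IP libraries, 5 correlated best with the input of their own letter. With a replicate block of strain by letter, 6500, 2023 and 29 bins passed, and 4 parts for set-25, the right parts of I, V and X and the left part of X. With the input of the same letter, a replicate block too, the X left contrasts of set-25 and N2 overlapped (exact permutation p = 0.3). The SD of the X left contrast in N2, met-2 and set-25 was then 0.055, 0.025 and 0.084, against 0.037, 0.013 and 0.073 with the mean input. For the arm contrast it was 0.23, 0.05 and 0.22, against 0.21, 0.07 and 0.19. With a replicate block across strains, 7099, 3853 and 128 passed. DESeq2 and gene tests were not run, and no filter is void because the filter removed 0 bins. With every library thinned to 8.73 M reads the arm contrast of met-2 minus N2 was -0.70. What depth limits among bins was not tested.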

Other observations

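The tests of borders, dilution, pull-down yield, column letter and splits were chosen after the results were seen, and the test of depth was not. When each autosome was fitted with 3 constant levels of LEM-2 enrichment, each at least 200 kb long, the depleted centre of N2 spanned 3.68 to 10.84 Mb on I in all 3 libraries. In met-2 the fitted borders were at 4.61 ± 0.03 and 12.08 Mb. The left border of II was at 4.64 ± 0.08 Mb in N2 and 2.68 ± 0.02 Mb in met-2 (SD, n = 3), and the right border of IV at 13.22 ± 0.02 and 13.54 Mb. The right border of II was at 11.98 Mb in both. Other borders were not stable within a strain: the left border of V ran from 0.89 to 9.2 Mb over the 3 met-2 libraries, and that of IV from 2.59 to 6.97 Mb over the libraries labelled set-25. In 6 of 10 borders the met-2 and N2 libraries did not overlap, against 2 of 10 for libraries labelled set-25. In each of these the exact permutation p was 0.1, the smallest possible, and 0.25 after adjustment over 20 tests. A fitted border can move when the profile is flatter, and the libraries of a strain share 1 input mean. These values therefore do not show that the depleted centre itself moved.

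The weaker arm contrast in met-2 was weighed against technical explanations. Depth does not account for it: with every library thinned to 8.73 M reads the difference from N2 was -0.70. The highest of the 3 within-letter differences was -0.52. With every met-2 library below every N2 library it had to lie below 0, so its sign is no test of a batch marked by the column letter. Each letter holds an IP and an input of every strain. A letter effect that is equal in all strains on the log2 scale therefore cancels in the difference of the means. A letter effect that differs by strain was not tested. An even dilution of the N2 profile with input-like fragments was fitted with 1 share per library. After it 11 of 18 parts lay outside the N2 residuals in all 3 met-2 libraries, and 9 of 18 in all 3 labelled set-25. Chance gives 1.8 only if the libraries of both strains are alike in all else. N2 libraries were fitted to N2 libraries over the same inputs, while met-2 libraries had inputs of their own. A difference between inputs can thus move all 3 met-2 residuals at once, and the count cannot decide on an even dilution. The middle part of V was left at 0.14 ± 0.05 and the right part of I at -0.16 ± 0.06 (SD, n = 3). A lower pull-down yield as part of the cause cannot be told apart from a loss of contact, since the mean fitted share of 0.377 follows from either, and the mutation stays open as the biological explanation.

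The same fit describes N2 column a, with the strongest arm contrast, by a share of 1.293 of the mean of the other N2 libraries, with a root mean square residual of 0.037 over the 18 parts.

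For the counts of bins, the 6 IP libraries of a pair can be split in 10 ways, too few for a share under 0.05. In each pair 1 of the 10 splits, the real one, gave as many bins. The real split gave 6816, 3047 and 42 bins for met-2 against N2, set-25 against N2 and met-2 against set-25 (limma). The highest of the others gave 0, 0 and 1. Each of the others mixes both strains in both groups, which puts a strain difference into the spread, so their counts are no measure of chance.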
